A study of Mus musculus with 10 samples.

How the data were processed

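RNA was measured in mouse peritoneum from 10 libraries in 4 groups, formed by genotype (Mr1+/+ or Mr1-/-) and by intraperitoneal PBS or 4.25% peritoneal dialysis (PD) fluid. The labels give 3 libraries per Mr1+/+ group and 2 per Mr1-/- group. Nothing in the labels ties each library to an animal, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, poly-A RNA was selected and reverse-transcribed with random primers, and no step that marks the strand and no molecular identifiers are named. If neither was used, reads of a gene and of an overlapping antisense gene cannot be told apart, and PCR copies may be counted as reads. The authors deposited whole-number counts per gene symbol, not normalized, and the genome build is mm10 per the submitters' processing notes. The aligner, the counter and the annotation are not given in the sources used here. Genes with near-identical copies, such as the haemoglobin, amylase and trypsin families, have uncertain counts for that reason.

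The deposited counts summed to 14145635 to 16335799 per library. The table had 21899 rows, and rows sharing a symbol were summed, which left 21877 symbols. Of these, 97.0% matched a gene name in GENCODE M21, an annotation of the same build, which supplied the coordinates. All 10 columns matched a sample label.

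Libraries of each group were compared before any average was taken. Over genes with at least 10 counts in 2 libraries together, a chi-square per gene of 1 is Poisson counting noise. Mr1+/+ PBS replicates 1 and 2 gave 2.23 and Mr1-/- PD fluid replicates 1 and 2 gave 1.74, against 18.6 to 118 for the other 6 pairs of libraries within groups. A plain Poisson test still separates the libraries of both pairs. At counts of 10 to 30, the lowest compared, the other pairs gave 1.83 to 4.01, which holds variation between samples as well as counting noise, and the share of each was not separated. The near-identical pairs were therefore merged because over all counts they lay far below the other pairs, not for meeting Poisson noise. The counts of each pair were summed and the pair was counted as 1 sample, which left 8 samples: 2 of Mr1+/+ PBS, 3 of Mr1+/+ PD fluid, 2 of Mr1-/- PBS and 1 of Mr1-/- PD fluid. The lone Mr1-/- PD fluid sample is assumed to vary like the samples of the other groups. The same is assumed of the 1 sample left in a group when a library is left out, as in fits without Mr1+/+ PBS replicate 3. The design fixed before the data were examined had all 10 libraries as separate samples. The change was made after the libraries were compared and before the calls of the 2 fits were compared, and counts from the 10 libraries are given beside the main ones. Those counts understate the spread between samples if a near-identical pair is 1 sample sequenced as 2 libraries.

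Genes were kept with edgeR's filterByExpr by group, which left 15385 genes (14815 with the 10 libraries). Library sizes were scaled by TMM. Differences were tested with edgeR 4.0.16 (R 4.3.3), by quasi-likelihood F tests with robust shrinkage on 4 group means, for 5 contrasts, with 4 residual degrees of freedom before shrinkage. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors (SE) were derived from the log2 fold change and its F statistic. Levels are CPM, the counts scaled by TMM library sizes. Of 53 gene lists fixed before the data were examined, 52 had at least 5 tested members and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of each contrast. Camera with an estimated correlation and the fry rotation test were alternatives. None of the camera calls in any contrast held with an estimated correlation. Mr1 was compared between genotypes by an exact two-sided permutation test on log2 CPM. Correlations of fold changes between contrasts were set beside 100 simulations without any effect, which kept the shared libraries.

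Named genes followed a rule fixed before the data were examined. It takes Mr1, up to 8 called genes with the largest rise and up to 8 with the largest fall in each contrast (mean CPM of at least 5, no overlap between the samples of the groups, no predicted or clone-based symbol), and up to 4 called members of each list described or, with none called, up to 2 with the smallest p. It also takes 22 genes of fibrosis, inflammation, mesothelium and MAIT cells whatever their result. Some genes that the rule takes are not reported here. Pnlip, Muc2, Apoa1, Apob and Cyp3a11 fall outside the rule and were chosen after their values were seen.

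On simulated counts for 15385 genes with 100 genes changed 2-fold and 100 changed 4-fold, the fit recovered 18% and 70% of them for PD fluid in Mr1+/+, 2% and 52% for PD fluid in Mr1-/-, 10% and 55% for genotype under PBS, 8% and 50% for genotype under PD fluid, and 0% and 31% for the interaction. Unchanged genes made up 5.38%, 6.90%, 16.7%, 14.7% and 16.2% of the calls in that order (5, 4, 13, 10 and 6 genes), above the nominal 5% in each contrast. Each contrast was simulated without repeats, so these shares are rough. Alternatives were DESeq2 1.42.0, other scaling, other filters, only the groups compared, covariates for skeletal muscle, pancreatic acinar and adipocyte scores, a replicate block and leaving out each library. The 8-sample fit, the acinar and adipocyte covariates and the version with only the Mr1-/- PD fluid pair counted once were chosen after seeing the data. The 10 separate libraries were the design fixed at the start, and the replicate block on them was set out at the same time. Both became alternatives to the 8-sample fit only after the data were seen.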

Results

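The data are read counts of peritoneal tissue from mice with and without Mr1, the molecule that presents microbial vitamin B metabolites to mucosal-associated invariant T (MAIT) cells. Mice received PBS or 4.25% PD fluid, the glucose-rich dialysis solution, for 6 weeks. There were 3 libraries each of Mr1+/+ PBS and Mr1+/+ PD fluid and 2 each of Mr1-/- PBS and Mr1-/- PD fluid, with 14145635 to 16335799 counts per library. Replicates 1 and 2 of Mr1+/+ PBS differed by a chi-square per gene of 2.23, and replicates 1 and 2 of Mr1-/- PD fluid by 1.74. The other 6 pairs within groups gave 18.6 to 118. At summed counts of 10 to 30 the near-identical pairs gave 1.67 and 1.61, and the other pairs 1.83 to 4.01. Each near-identical pair thus differed by more than Poisson noise and by less than every other pair within groups, and was counted as 1 sample, so n is 2, 3, 2 and 1 for the groups in that order.

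**Figure D1:**
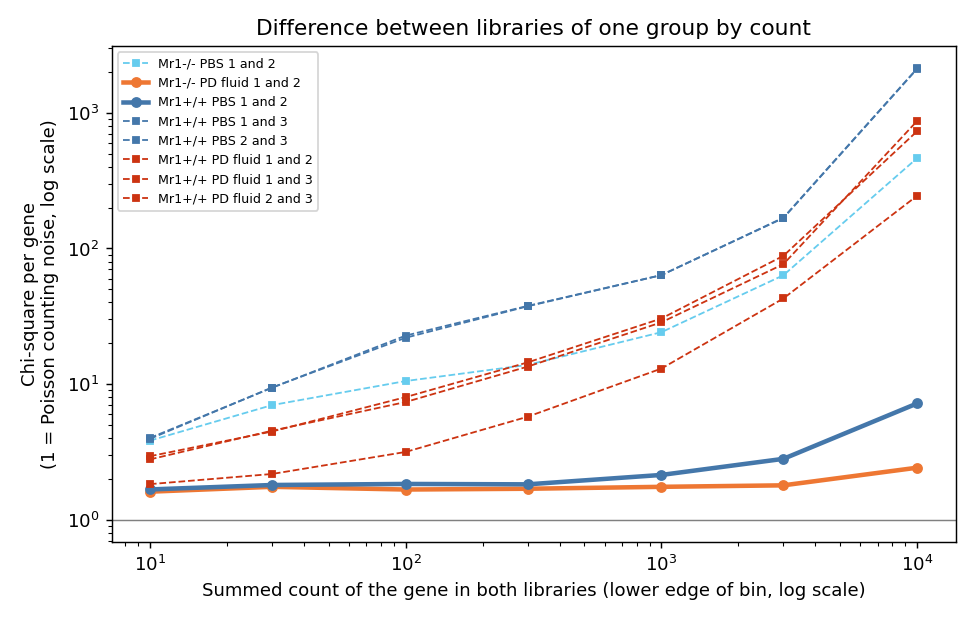
Chi-square per gene between 2 libraries of a group (y axis, log scale, 1 is Poisson noise) against the summed count of the gene (x axis, log scale, lower edge of each bin). The solid lines are the 2 near-identical pairs, which stay at 1.61 to 7.20, and the dashed lines are the other 6 pairs.

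Mr1 was low in every library labelled Mr1-/-. The gene (ENSMUSG00000026471.14; mm10 chromosome 1, 155127277 to 155146814, minus strand) had 27.7 ± 4.66 CPM (SD, n = 5) in Mr1+/+ and 2.25 ± 0.255 CPM (SD, n = 3) in Mr1-/- samples, a 12.3-fold difference. The log2 difference was -3.55 (exact two-sided permutation test over 56 splits, p = 0.0179, the smallest they can give). Mr1 counts were 324 to 524 in the 6 Mr1+/+ libraries and 29 to 39 in the 4 Mr1-/- libraries. Of 56 tested genes within 5 Mb of Mr1, edgeR called 0 in either genotype comparison, with 5 under PBS and 10 under PD fluid at an unadjusted p under 0.05. These shares, 8.93% and 17.9%, were near those over all tested genes, 8.64% and 19.1%. DESeq2 called 0 and 5 of the 56, and 215 and 1035 over all 15385 tested genes.

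Transcripts of other organs were present and unequal between libraries. Mr1+/+ PBS replicate 3 held the pancreatic lipase Pnlip at 5030 CPM and the intestinal mucin Muc2 at 664 CPM, while the other libraries held Pnlip at 29.9 to 953 CPM and Muc2 at 0.41 to 2.46 CPM. Pancreatic acinar genes took 3.21% of its counts. Alb, the liver's serum albumin gene, was at 64.4 to 109 CPM in the 4 Mr1-/- libraries and 0.19 to 2.18 CPM in the 6 Mr1+/+ libraries.

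**Figure D2:**
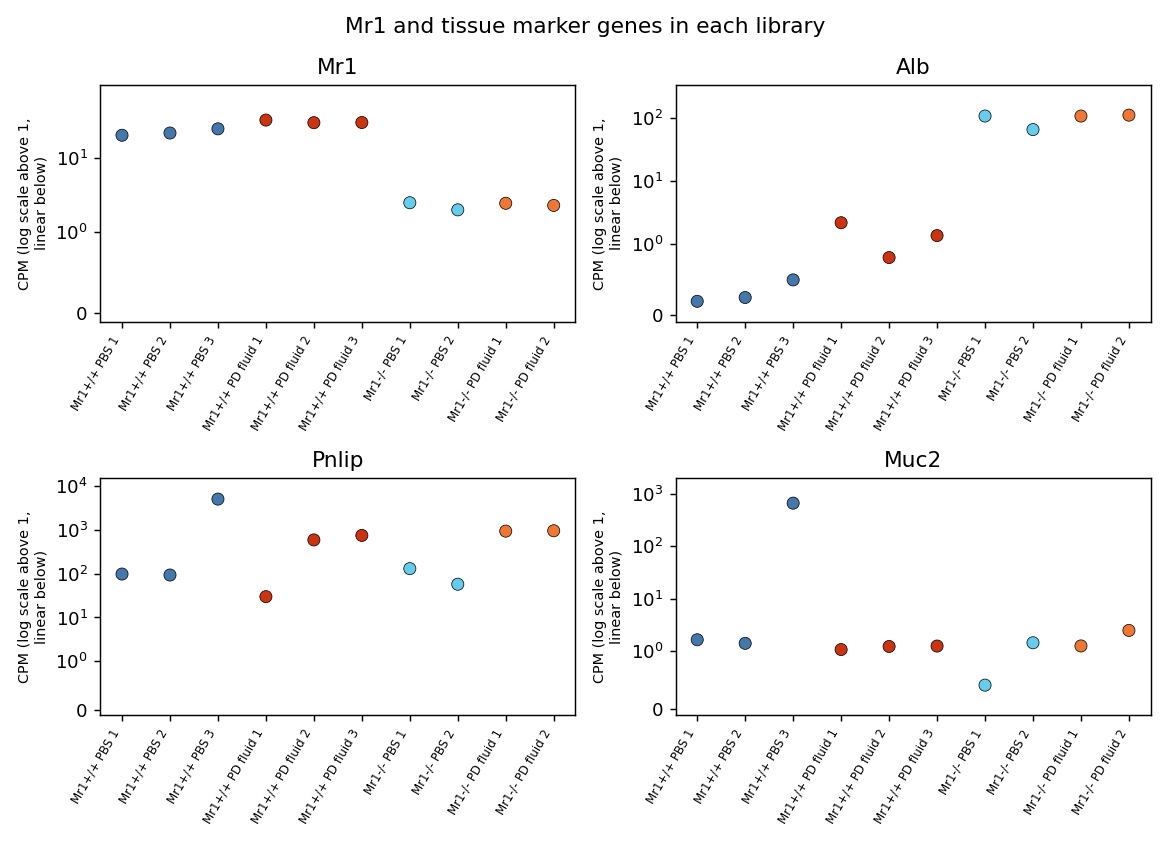
CPM (y axis, log scale above 1 and linear below) of Mr1, Alb, Pnlip and Muc2 in each library (x axis), coloured by group. Alb lies at 64.4 CPM or more in every Mr1-/- library, and Muc2 reaches 664 CPM in Mr1+/+ PBS replicate 3.

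The first comparison asks how PD fluid changed the peritoneum of Mr1+/+ mice. Of 52 gene lists, camera called 25 higher after PD fluid, among them adipocyte, matrix, endothelial and macrophage lists, and 5 lower, among them B cell and cell cycle lists. With an estimated correlation none of these calls held (smallest adjusted p = 0.37). Col1a1, the main fibrillar collagen chain, went from 218 ± 14.4 CPM (SD, n = 2) to 544 ± 114 CPM (SD, n = 3), and Col3a1 from 426 ± 89.8 to 1731 ± 560 CPM. The B cell lineage factor Pax5 went from 367 ± 105 to 119.7 ± 21.6 CPM. In all, 1306 genes rose and 980 fell at an edgeR adjusted p under 0.05, of 15385 tested. With the 10 libraries as separate samples the counts were 2842 and 2707, and DESeq2 called 3852. With the skeletal muscle covariate 611 genes were called, 455 of them among the 2286 main calls. Without Mr1+/+ PD fluid replicate 3 no gene passed (3601 at an unadjusted p under 0.05), without replicate 2 of that group 339 passed, and without Mr1+/+ PBS replicate 3 the count was 2751.

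Of 19 adipocyte markers, 16 rose (19 adjusted over the list alone), with a median log2 fold change of 1.62. They included Car3 (1.82, SE 0.24), the fat cell adrenergic receptor Adrb3 (1.65, SE 0.23), the adipogenic factor Cebpa (1.47, SE 0.20) and the complement factor Cfd, or adipsin (1.89, SE 0.27). Of 26 lipid synthesis genes, 14 rose and 1 fell (20 and 1 adjusted over the list alone). The triglyceride enzyme Dgat2 went from 226 ± 0.02 to 673 ± 22 CPM, and Thrsp, Agpat2 and Insig1 rose by 1.95, 1.43 and 1.43 on the log2 scale. Of 27 fatty acid oxidation genes, 13 rose (16 and 1 fall adjusted over the list alone), among them Decr1, Echs1, Eci1 and Acsl1. With the mean log2 CPM of the adipocyte markers, the adipocyte score, as a covariate camera called this list lower (adjusted p = 0.028). Without the covariate the adjusted camera p was 3.8e-11, 6.3e-09 and 3.7e-06 for these 3 lists (with an estimated correlation, adjusted p = 0.37, 0.37 and 0.46).

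Of 28 genes for fibrillar collagens and matrix proteins, 21 rose (23 and 1 fall adjusted over the list alone), with a median log2 fold change of 1.36 and an adjusted camera p of 1.7e-10 (adjusted p = 0.37 with an estimated correlation). Fbln1, a matrix glycoprotein, rose by 1.54 (SE 0.16), Col5a2 by 1.46 (SE 0.19), Col5a1 by 1.46 (SE 0.22) and the collagen crosslinker Loxl2 by 1.11 (SE 0.17). Col1a2 rose by 1.32 (SE 0.21). The adipocyte score was higher in all 3 Mr1+/+ PD fluid samples than in the other 5 samples, and with that score as a covariate 63 genes passed, Col1a1 was at -0.12 (SE 0.55) and Col3a1 at -0.83 (SE 0.60). Of 15 fibroblast markers, 10 rose (11 and 1 fall adjusted over the list alone), among them Dpt, Scara5, Serpinf1 and Cd34 (adjusted camera p = 3.7e-06; adjusted p = 0.37 with an estimated correlation). Among 24 TGF-beta pathway genes, 7 rose, including Ltbp3 and Tgfb3, and 2 fell, the pathway inhibitor Smad7 (-1.18, SE 0.14) and the repressor Tgif1 (8 and 2 adjusted over the list alone). This list had an adjusted camera p of 0.024 (adjusted p = 0.37 with an estimated correlation), 0.089 without Mr1+/+ PBS replicate 3 and 0.053 without Mr1+/+ PD fluid replicate 2. Ccn2, a matrix-associated growth factor, rose by 1.58 (SE 0.38, adjusted p = 0.037) and Vegfa by 0.93 (SE 0.23, adjusted p = 0.035). Fn1 (0.77, SE 0.34), Acta2 (0.87, SE 0.40), Postn (1.02, SE 0.46) and Tgfb1 (-0.23, SE 0.19) did not pass. Without Mr1+/+ PBS replicate 3, Postn was 2.06 and passed (adjusted p = 0.0076), and Tgfb1 was -0.50 (adjusted p = 0.064).

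**Figure D3:**
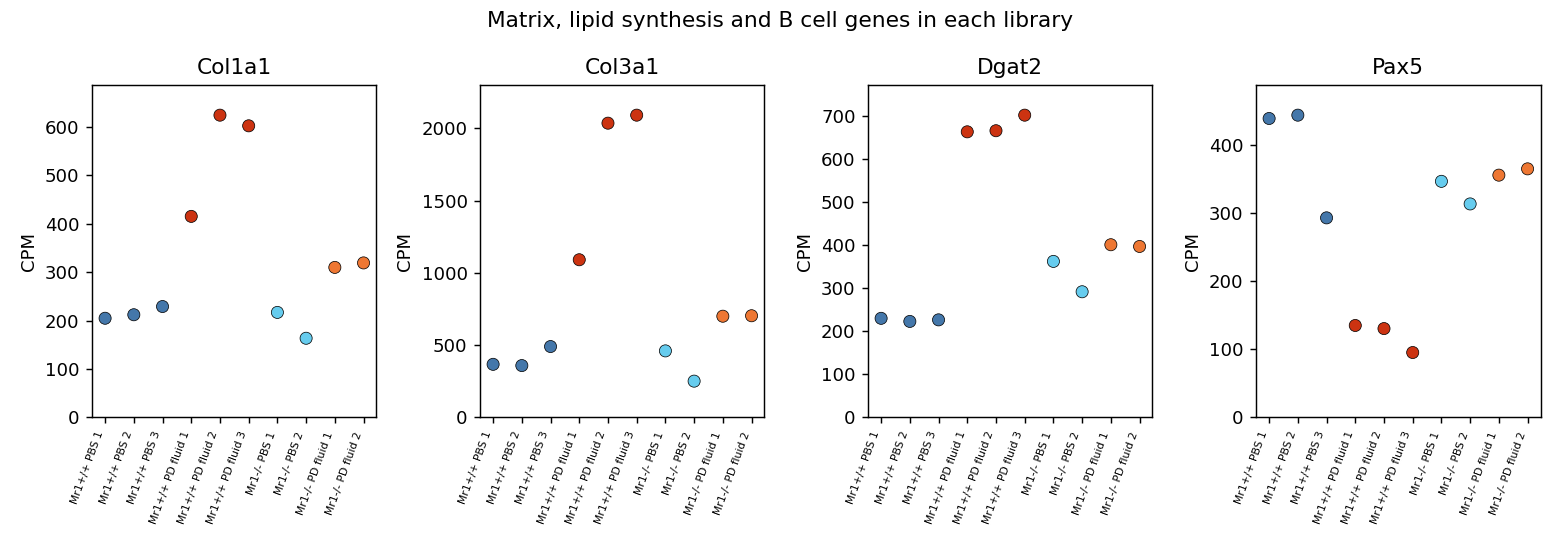
CPM (y axis, linear from 0) of Col1a1, Col3a1, Dgat2 and Pax5 in each of the 10 libraries (x axis), coloured by group. In Mr1+/+ PD fluid libraries Col1a1 lies at 415 to 624 CPM and Pax5 at 95.4 to 135 CPM.

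Of 21 endothelial and angiogenesis genes, 14 rose (20 adjusted over the list alone), including Tie1 (1.04, SE 0.16) and Esam (1.41, SE 0.24), with an adjusted camera p of 2.5e-09 (adjusted p = 0.37 with an estimated correlation). Of 19 macrophage and monocyte markers, 7 rose (10 adjusted over the list alone). The scavenger receptor Cd163 went from 35.1 ± 9.49 to 113 ± 13.8 CPM, and Mrc1, Ccr2, Itgam and Adgre1 rose by 1.20, 1.53, 1.55 and 1.49 on the log2 scale. Cd68 (0.45, SE 0.25; 0.28 without Mr1+/+ PBS replicate 3) did not pass. The list had an adjusted camera p of 6.1e-05 (adjusted p = 0.37 with an estimated correlation). Erythroid genes were higher in the same samples, with a median of 2.37. Il6, Il1b, Tnf and Ccl2 had at most 14, 54, 143 and 265 counts in any library. At such counts a change of Il6 or Il1b would be hard to see. None of these genes passed, with log2 fold changes of 0.56, 0.60, 0.31 and 0.44. Without Mr1+/+ PBS replicate 3 these were 0.90, 0.86, -0.021 and -0.0025, and again none passed. Il17a and Ifng, at no more than 8 and 1 counts in any library, were not tested.

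Of 14 B cell markers, 11 fell (12 adjusted over the list alone), among them Pax5 (-1.62, SE 0.22), Cd22 and Fcrla (adjusted camera p = 7.9e-06; adjusted p = 0.42 with an estimated correlation). Of 17 T cell markers, 4 fell (8 adjusted over the list alone), among them Cd28, Cd6 and Cd5 (adjusted camera p = 6.7e-05; adjusted p = 0.49 with an estimated correlation). With the adipocyte score as a covariate camera called the T cell list higher (adjusted p = 0.00074). Of 25 cell cycle genes, 15 fell (21 adjusted over the list alone), among them the mitotic kinase Plk1 (-1.58, SE 0.22) and the topoisomerase Top2a (-1.15, SE 0.17), with an adjusted camera p of 2.1e-09 (adjusted p = 0.40 with an estimated correlation). Among 21 MAIT and innate-like T cell genes, 3 rose and 3 fell (6 and 3 adjusted over the list alone), among them the chemokine receptor Ccr6 (-1.24, SE 0.23), the kinase Blk (-0.94, SE 0.20) and the transcription factor Maf (0.83, SE 0.16). Blk is also on the B cell list, so its fall cannot be assigned to either cell type. The camera adjusted p of the MAIT and innate-like T cell list was 0.24. Zbtb16, the transcription factor of MAIT and natural killer T cells, was at 22.9 ± 14.3 and 134 ± 85.6 CPM and did not pass (adjusted p = 0.11). It is also on the glucocorticoid response list, so its level cannot be assigned to MAIT cells. The mean log2 CPM of that list, Zbtb16 included, was 6.02 to 6.56 in the Mr1+/+ PBS libraries. In the Mr1+/+ PD fluid libraries it was 7.04 to 7.16.

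Of 26 complement and coagulation genes, 12 rose (17 adjusted over the list alone), among them the tissue factor gene F3 (1.39, SE 0.16) and the complement proteases C1s1 and C1ra. Of 23 matrix proteases and inhibitors, 10 rose (16 adjusted over the list alone), including Mmp19 (1.74, SE 0.24), Mmp12 (3.76, SE 0.68) and the inhibitor Timp2 (0.85, SE 0.16). Of 20 basement membrane genes, 11 rose and 2 fell (14 and 2 adjusted over the list alone), with Lamb2 at 0.99, Col4a2 at 1.18 and the epithelial laminin chain Lamb3 at -1.91 (-1.21 without Mr1+/+ PBS replicate 3, the library with intestinal transcripts). Of 15 neutrophil markers, 4 rose (7 adjusted over the list alone): Lcn2, Mmp9, S100a9 and Elane. The adjusted camera p was 4.3e-09, 1.8e-06, 0.00013 and 0.0013 for these lists (with an estimated correlation, adjusted p = 0.37, 0.37, 0.46 and 0.49). Of 6 erythroid genes, 3 rose (5 adjusted over the list alone), with a median of 2.37 and a camera adjusted p of 0.0013 (adjusted p = 0.42 with an estimated correlation). Their mean log2 CPM was 2.52 to 3.95 in the Mr1+/+ PD fluid libraries and 0.72 to 1.40 in the Mr1+/+ PBS libraries.

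Among genes that met the limits for named genes (mean CPM of at least 5, no overlap between the samples of the groups), the largest rises were as follows. They were in S100a9, Hp, Lcn2, Timp1, Orm1, Apoc1, Pf4 and Hbb-bt. The acute-phase haptoglobin gene Hp went from 120 ± 7.73 to 1431 ± 760 CPM, and the neutrophil gene S100a9 from 0.54 ± 0.37 to 9.49 ± 6.40 CPM. Under the same limits the largest falls were in Aoc1, Sgpp2, Cracd, Crybg2, Dsc2, Bspry, Tjp3 and Cubn. All 8 were highest in Mr1+/+ PBS replicate 3, the library with intestinal transcripts. Without that library Aoc1 moved from -4.18 to -2.01 and Bspry from -3.16 to -1.16, and Sgpp2, Cracd, Crybg2 and Bspry lost their calls. S100a9, Lcn2, Timp1 and Apoc1 also lost their calls, at log2 fold changes of 3.56, 3.25, 2.77 and 2.65 without that library against 4.05, 3.48, 3.17 and 2.67 with it.

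The second comparison asks the same of Mr1-/- mice, with 1 PD fluid sample against 2 PBS samples. Fbln1 was 1.49 (SE 0.20, adjusted p = 0.43) and Cd163 1.71 (SE 0.27, adjusted p = 0.93) on the log2 scale. Col1a1 was at 0.73 and Col3a1 at 0.98, without passing. No gene was called by edgeR, with 231 at an unadjusted p under 0.05, and DESeq2 called 12. The 231 genes are fewer than 5% of the 15385 tested, the share that p-values without any effect would give. The 5% benchmark therefore does not describe these p-values, and the count is no sign for or against a weak effect. With the 10 separate libraries the count was 765 of 14815 tested. The spread of the lone PD fluid sample is assumed from other groups. The lack of calls therefore cannot be set against the number of calls in Mr1+/+. The 10 separate libraries gave 2 calls. Camera called 18 lists higher and 5 lower. Fibrillar collagens and matrix proteins (27 of 28 positive, median 0.57, camera adjusted p = 7.0e-16), fibroblast markers (median 0.57, and 0.87 without Mr1-/- PBS replicate 1), macrophage and monocyte markers (median 0.48) and mesothelial markers (18 of 18 positive) were higher. In that order, with an estimated correlation, the adjusted p was 0.21, 0.19, 0.19 and 0.30, and the smallest fry adjusted p over the 52 lists was 0.31. Msln (0.91), Upk3b (1.59) and Wt1 (1.43), mesothelial genes, did not pass. Pancreatic acinar and erythroid genes were also higher in this comparison, with medians of 3.44 and 1.58, and the erythroid list had a camera adjusted p of 2.9e-05 (adjusted p = 0.30 with an estimated correlation, and 0.074 without Mr1-/- PBS replicate 1). In simulated data with this layout 52% of 4-fold and 2% of 2-fold changes were recovered.

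Under PBS, with 2 samples of each genotype, 2 genes changed: Mr1 fell (-3.37, SE 0.22, adjusted p = 0.00358) and Alb rose (8.05, SE 0.58, adjusted p = 0.0154). Alb lies on mm10 chromosome 5, 90460897 to 90476602, plus strand. At an unadjusted p under 0.05 there were 1329 genes, DESeq2 called 215 and the 10 separate libraries gave 50. Of 16 liver genes, 1 rose (9 adjusted over the list alone), with adjusted camera p = 3.5e-17 (adjusted p = 0.48 with an estimated correlation). All 11 mitochondrially encoded genes were positive, with a median of 1.25 and adjusted camera p = 5.4e-08 (adjusted p = 0.66 with an estimated correlation). Adjusted over the list alone 8 of them rose, and mt-Nd2 was 1.32 (SE 0.24) without passing over all genes. With only these 2 groups in the fit neither Mr1 (-3.39) nor Alb (8.03) passed (adjusted p = 0.217 for each). Alb (8.03) also did not pass without Mr1+/+ PD fluid replicate 3 (adjusted p = 0.270). The log2 fold changes thus stayed about as large where the calls were lost.

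Under PD fluid, with 1 Mr1-/- sample against 3 Mr1+/+ samples, camera called adipocyte, matrix and endothelial lists lower in Mr1-/- and B cell and cell cycle lists higher. With an estimated correlation none of these 5 calls held (adjusted p = 0.49 for each list). Among single genes edgeR called 2, Mr1 (-3.72, SE 0.28) and Alb (6.19, SE 0.45), at adjusted p = 0.0130 and 0.0165. With the adipocyte score as a covariate neither passed (-3.48 and 6.61, adjusted p = 0.0657 and 0.358). At an unadjusted p under 0.05 there were 2932 genes, DESeq2 called 1035 and the 10 separate libraries gave 1754 higher and 1646 lower. EdgeR also called many more genes with only the groups compared and with the acinar covariate, with the counts given below. All 19 adipocyte markers were negative (median -1.21, camera adjusted p = 6.9e-10), with Adrb3 at -1.34 (SE 0.29) and Cebpa at -1.21 (SE 0.26). Of 28 matrix genes 26 were negative (median -0.82, camera adjusted p = 1.0e-07), with Loxl2 at -1.03 (SE 0.22) and Col1a1 at -0.80. All 14 B cell markers were positive (median 1.04, camera adjusted p = 1.2e-07), with Pax5 at 1.58 (SE 0.26). All 21 endothelial and angiogenesis genes were negative (median -0.82, camera adjusted p = 5.7e-08), and all 25 cell cycle genes were positive (median 0.68, camera adjusted p = 1.2e-07). Adjusted over the list alone, 15 adipocyte markers, 10 matrix genes and 7 endothelial genes fell and 12 B cell markers and 8 cell cycle genes rose. The chemokine Ccl2 was 2.40 (SE 0.51) and S100a9 -5.38 (SE 1.29), both with adjusted p = 0.15. Without Mr1+/+ PD fluid replicate 2 or 3 edgeR called 0 genes (2206 and 1768 at an unadjusted p under 0.05), and without Mr1+/+ PBS replicate 3 the count was 33.

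**Figure D4:**
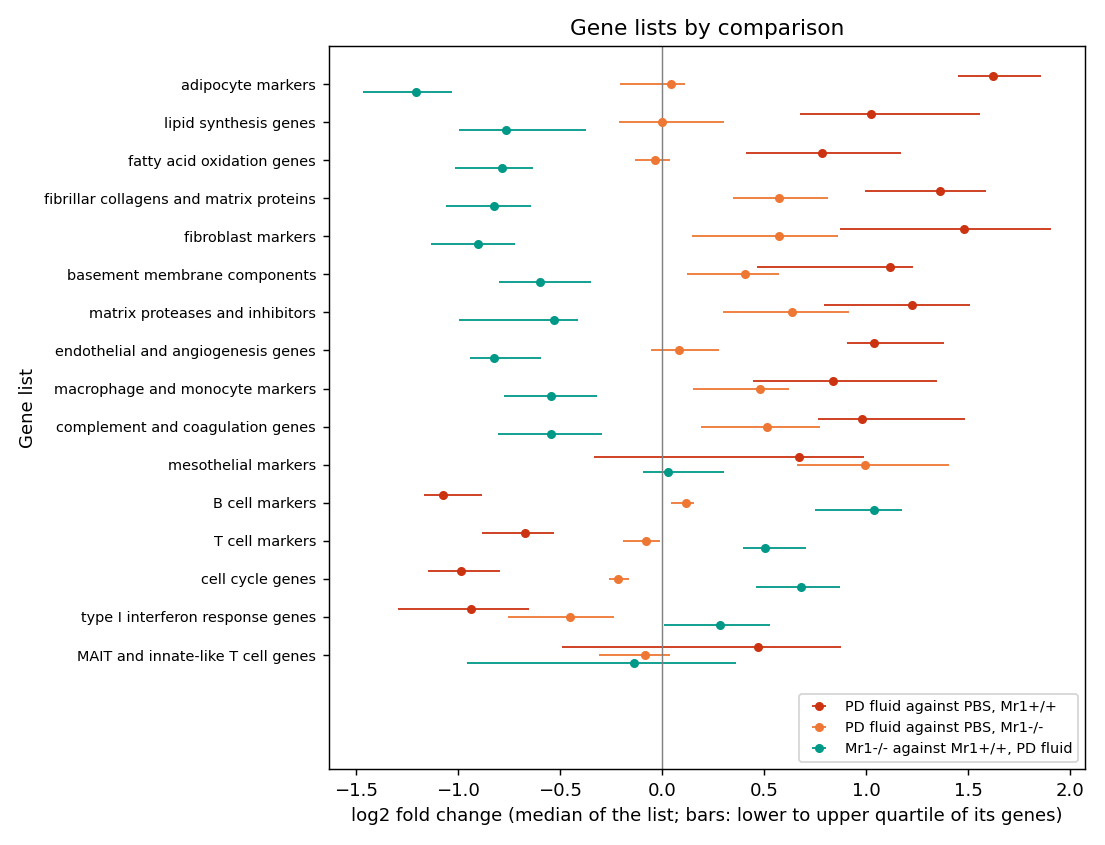
Median log2 fold change of the genes of 16 lists (x axis; bars from the lower to the upper quartile of the genes) for 3 comparisons, with a list per row on the y axis. Adipocyte markers lie at 1.62 for PD fluid in Mr1+/+ and at -1.21 for Mr1-/- against Mr1+/+ under PD fluid.

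The interaction asks whether PD fluid changed genes differently in the genotypes. No single gene was called by edgeR (2037 at an unadjusted p under 0.05), DESeq2 called 488 and the 10 separate libraries gave 646 higher and 844 lower. With a muscle, acinar or adipocyte covariate edgeR did call genes, with the counts given below. Adrb3 was -1.87 (SE 0.37), Dgat2 -1.28 (SE 0.26) and Pax5 1.74 (SE 0.36), each with adjusted p = 0.27. Among 52 lists camera called 7 higher and 17 lower, with adipocyte markers at a median of -1.77, and the smallest adjusted p with an estimated correlation was 0.65.

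Of the 2286 genes called for PD fluid in Mr1+/+, 55.6% had the same sign in Mr1-/-. The genes that rose had a median log2 fold change of 1.09 in Mr1+/+ and 0.09 in Mr1-/-, and those that fell -0.86 and 0.02. These genes were chosen by their size in Mr1+/+, which enlarges that side. Over all genes, which are not independent replicates, Pearson's r between the PD fluid changes in the genotypes was -0.07 (-0.01 ± 0.03 in 100 simulations without effects), and Spearman's rho had the opposite sign, at 0.0877 (0.00042 ± 0.0083 in the simulations, 0.0165 at most). EdgeR called 0 genes in Mr1-/-, so its count of genes called in both had to be 0 (9 by DESeq2). Without Mr1+/+ PBS replicate 3, r was 0.29, and leaving out each of the 10 libraries in turn gave r a jackknife SE of 0.356. Leaving out 1 library of a near-identical pair keeps the sample formed by that pair. The SE thus does not measure the spread between the 8 samples. The same SE was not computed for rho. Between PD fluid in Mr1+/+ and genotype under PD fluid, which share the Mr1+/+ PD fluid libraries, r was -0.50 (simulated -0.32 ± 0.03) and the covariance -0.64 (simulated -0.18 ± 0.02). The lowest simulated values were -0.381 and -0.231. The jackknife SEs of the observed r and covariance, with the limit given above, were 0.136 and 0.289. They therefore cannot show whether either value lies outside the spread between samples. EdgeR called 0 genes in opposite directions (0.149 expected from independent lists, 939 by DESeq2). Only 2 genes were called for genotype under PD fluid, so this count could hardly differ from 0. With the 10 separate libraries that count was 2683 (636 expected from independent lists). Part of any excess can come from the shared libraries, which were too few to divide.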

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

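The interaction and its list tests, the fits without each library and the count of other splits were planned. The tests with the adipocyte score, of the near-identical pairs and of the liver genes, and the use of the fit without Mr1+/+ PBS replicate 3 to test an explanation, were chosen after the results they bear on had been seen. The difference between the genotypes in their response to PD fluid was tested as an interaction, and 24 gene lists passed camera with the preset correlation, while none passed with an estimated correlation (smallest adjusted p 0.65) or with fry (smallest 0.19). Lower in Mr1-/-, by median interaction log2 fold change, were adipocyte markers (-1.77), lipid synthesis genes (-1.11), endothelial and angiogenesis genes (-0.99), fatty acid oxidation genes (-0.84), mitochondrially encoded genes (-1.32), oxidative phosphorylation, nuclear-encoded (-0.51), heat shock genes (-0.97), fibrillar collagens and matrix proteins (-0.55), complement and coagulation genes (-0.53), oxidative stress response genes (-0.64), fibroblast markers (-0.75), hypoxia response genes (-0.54), nerve and Schwann cell markers (-0.99), mesenchymal transition genes (-0.71), neutrophil markers (-2.34), myofibroblast and smooth muscle contractile genes (-1.18), matrix proteases and inhibitors (-0.51). Higher in Mr1-/-, by the same value, were B cell markers (1.15), cell cycle genes (0.78), plasma cell genes (1.04) and pancreatic acinar genes (5.82). So were T cell markers (0.57), immediate early genes (0.52) and intestinal epithelial genes (8.64). Lower and higher here describe the change with PD fluid in Mr1-/- relative to that in Mr1+/+, not levels. Mitochondrially encoded genes, for example, are on the lower side here but were higher in Mr1-/- under PBS. Without Mr1+/+ PBS replicate 3, which holds pancreatic and intestinal transcripts, the acinar value was 1.08 and the intestinal value 0.77, and neither passed (camera adjusted p = 0.10 and 0.15). Without Mr1-/- PBS replicate 2, whose mean log2 CPM of contractile genes was 7.89 against 6.14 in replicate 1, myofibroblast and smooth muscle contractile genes were at 0.11 (camera adjusted p = 0.72) and neutrophil markers at -1.20 (camera adjusted p = 0.11), and heat shock genes (-0.55) and nerve and Schwann cell markers (-0.54) still passed. Without Mr1-/- PBS replicate 1, contractile genes were at -1.79 and fibroblast markers at -0.48, both still passing, while matrix proteases and inhibitors (-0.12) and mesenchymal transition genes (-0.46) did not pass (camera adjusted p = 0.62 and 0.11). Contractile genes, neutrophil markers and mesenchymal transition genes also lost their calls without Mr1+/+ PBS replicate 3 (-1.05, -1.75 and -0.52), as did contractile genes, neutrophil markers and matrix proteases without Mr1+/+ PD fluid replicate 2 (-1.17, -2.21 and -0.42) and contractile genes without replicate 1 of that group (-1.17). With an adipocyte score as a covariate, camera called the matrix list higher and the T cell list lower (adjusted p = 0.017 and 0.00042).

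The 2 near-identical pairs differed, for genes of 3000 counts or more, by a CV of 3.19% at most, against 11.4% for the closest of the other 6 pairs within groups and 7.11% for the closest pair of different groups, Mr1-/- PBS replicate 1 and Mr1-/- PD fluid replicate 1. Both pairs thus varied less than the other pairs compared, but they were picked for their closeness and the 3.19% measures it again. It is therefore no separate test of whether the libraries of a pair come from separate animals. In the other 6 pairs within groups chi-square per gene rose steeply with the count, as from 3.83 to 464 for Mr1-/- PBS. For the Mr1-/- PD fluid pair it went only from 1.61 at the lowest counts to 2.42 at 10000 or more. These values argue against 2 animals for that pair, unless the animals hardly varied. For the Mr1+/+ PBS pair it went from 1.67 to 7.20. Whether that pair is 1 RNA sample sequenced as 2 libraries or 2 unusually alike animals cannot be told apart. No biological explanation was tested.

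Alb was not alone in following genotype, since 10 of 13 other liver genes were higher in every Mr1-/- sample than in every Mr1+/+ sample. For 12 of these 13 genes, all but the lowest in Mr1-/-, the ratios to Alb varied by a mean CV of 10.2% over the 3 Mr1-/- samples. Alb itself varied by a CV of 26.2%, or 1.67-fold at most, too little for the ratios to separate liver RNA from an effect of genotype. Apoa1, Apob and Cyp3a11, which were not higher in every Mr1-/- sample, were highest in Mr1+/+ PBS replicate 3, which holds intestinal transcripts. No Mr1+/+ sample had Alb above 2.17 CPM and the labels name no batch, so handling or a library batch that follows genotype cannot be told apart from genotype itself. An effect of Mr1 loss on liver genes in peritoneum stays open and untested.

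Without Mr1+/+ PBS replicate 3 the log2 fold change with PD fluid in Mr1+/+ was 1.39 for Col1a1, 2.26 for Col3a1 and -1.88 for Pax5. With that library these were 1.32, 2.02 and -1.62, while Aoc1 moved from -4.18 with it to -2.01 without it. The fit without it leaves 1 Mr1+/+ PBS sample and takes the spread from the other groups. Its count of calls therefore cannot settle whether that library set the calls. With an adipocyte score as a covariate 63 genes were called, and Col1a1 went from 1.32 (SE 0.22) to -0.12 (SE 0.55). The score was higher in all 3 Mr1+/+ PD fluid samples (8.88 to 9.40) than in the other 5 (7.37 to 8.18). More fat tissue in those samples may therefore account for the calls or may be part of the response, and the 2 cannot be told apart because the score separates the groups. The 10 splits of the 5 Mr1+/+ samples are too few for a share under 0.05: the real split gave 2286 calls (1 split with as many) and the highest other 2.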

How the results depend on the processing

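The 10 separate libraries were the design fixed before the data were examined, and the replicate block on them was set out at the same time. Both became alternatives to the 8-sample fit only after the data were seen. The 8-sample main fit, the single merged pair and the acinar and adipocyte covariates were chosen after the data were seen. Main counts were 2286 (PD fluid in Mr1+/+), 0 (PD fluid in Mr1-/-), 2 (genotype under PBS), 2 (genotype under PD fluid) and 0 (interaction), and the cause of each change below was not tested unless given. DESeq2 gave 3852, 12, 215, 1035 and 488, with 939 opposed and 9 shared calls. The muscle covariate gave 611, 2, 7, 20 and 39, the acinar covariate 6, 573 and 227 for the last 3, and the adipocyte covariate 63, 105, 23 and 41 for all but PD fluid in Mr1-/-. No filter gave 6 and 7 and the stricter filter 5 and 7 for genotype under PBS and PD fluid. Only the groups compared gave 0 and 561 for these, and a log2 fold change of at least 1 left 1064 genes for PD fluid in Mr1+/+ by construction. With 10 separate libraries the counts were 5549, 2, 50, 3400 and 1490, with 2683 opposed and 2 shared calls, and the added samples raise the residual degrees of freedom. Any fit that keeps a near-identical pair apart also understates the spread if that pair is 1 sample. With only the Mr1-/- PD fluid pair counted once, PD fluid in Mr1+/+ had 4548 calls and 1 call was opposed. Over 13 same-numbered pairs the correlation of deviations from group means was -0.13 to 0.15, with 1 above 0.1. In a group of 2 libraries these deviations mirror each other, and between near-identical libraries they are small. The check therefore showed no pairing by replicate number but cannot exclude it. The replicate block with 10 separate libraries gave 5537 calls for PD fluid in Mr1+/+, 2428 for genotype under PD fluid and 1915 for the interaction, with 0 and 3 for the other contrasts, 2016 opposed calls and an opposed correlation of -0.69. The block was not run on the summed pairs, which carry 2 replicate numbers each. Leaving out each library gave 0 to 2751, 0 to 1, 1 to 3, 0 to 33 and 0 to 1 calls, 0 to 10 opposed calls, an opposed correlation of -0.58 to -0.42 and a covariance of -0.84 to -0.45, and a correlation of -0.20 to 0.29 between the PD fluid changes of the genotypes. Of 30, 23, 11, 22 and 24 lists called, an estimated correlation left 0 in each contrast and fry called 19, 0, 1, 1 and 0, of which 17, 0, 1, 1 and 0 were among them. The adipocyte covariate gave 13, 24, 10 and 13 lists for all contrasts but PD fluid in Mr1-/-. Lists called in both fits turned direction with that covariate: for PD fluid in Mr1+/+ T cell markers and type I interferon genes from lower to higher (camera adjusted p = 0.00074 and 8.8e-11) and oxidative phosphorylation and fatty acid oxidation genes from higher to lower (0.0033 and 0.028), for genotype under PD fluid T cell markers from higher to lower (0.0022), and for the interaction T cell markers from higher to lower (0.00042) and matrix genes from lower to higher (0.017). Without Mr1-/- PBS replicate 2 contractile genes turned from lower to higher for PD fluid in Mr1-/- (0.011). For genotype under PBS the muscle covariate gave 17 and the acinar covariate 21. The Mr1 difference kept its direction and exact p under 0.05 in every setting, at -3.61 to -3.46 without each library. RLE factors, library size only and no robust shrinkage moved no count by over 1.5 times. For single named genes over all settings, 540 results lost a call, 587 gained 1 and 13915 kept sign and side. A sign change without a call in either fit occurred 173 times. Called genes turned direction 30 times, all 30 for PD fluid in Mr1+/+ with the adipocyte covariate and with the call lost there, at log2 fold changes of Timp1 -0.62, Orm1 -0.39, Apoc1 -0.996, Pf4 -1.36, Col1a1 -0.12, Col3a1 -0.83, Ccn2 -0.64, Vegfa -0.76, Col15a1 -0.045, Mmp12 -0.23, Tgfb3 -0.58, Prrx1 -0.14, Esam -0.31, Ccr2 -0.35, Itgam -0.83, Vsig4 -1.56, Fcna -0.17, Chil3 -1.78, Mmp9 -0.056, Elane -0.82, Hdc -0.80, Cd28 0.16, Cd6 0.68, Cd5 0.62, Pou2af1 0.54, Procr -0.059, Decr1 -0.15, Echs1 -0.087, Eci1 -0.15, Acsl1 -0.16. With 1 to 3 samples per group, 2-fold changes were mostly missed in simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Where many more genes change, as with PD fluid in Mr1+/+, the adjusted threshold is less strict. The simulated shares need not hold there.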

Other observations

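The list tests in this part were planned, and which lists to describe here was chosen after their results were seen. Of 12 heat shock genes, Cryab, Hspb1 and Bag3 rose with PD fluid in Mr1+/+ (1.87, 1.70 and 0.68 on the log2 scale; 3 adjusted over the list alone), and without Mr1+/+ PBS replicate 3 Bag3 was 0.71 and lost its call. Of 20 oxidative stress response genes 8 rose and 1 fell (12 and 1 adjusted over the list alone), and the extracellular antioxidant enzymes Gpx3 and Sod3 were at 1.33 (SE 0.14) and 1.44 (SE 0.17). Of 16 hypoxia response genes 8 rose (9 and 2 falls adjusted over the list alone), including the mitophagy gene Bnip3 (1.46, SE 0.23) and the collagen prolyl hydroxylases P4ha1 and P4ha2, of which P4ha1 lost its call without that library (1.06 to 0.98). Of 21 MHC class I and class I-like genes 4 rose and 3 fell (5 and 4 adjusted over the list alone), and the lipid-presenting Cd1d1 was among those that rose (1.30, SE 0.18). Of 21 type I interferon response genes 19 were negative with a median of -0.94, and Ifit1 was at -2.02 (SE 0.74, adjusted p = 0.12). This list varied widely within groups. Its mean log2 CPM was 6.06, 6.05 and 5.11 in Mr1+/+ PBS replicates 1, 2 and 3 and 4.55 to 4.98 in the Mr1+/+ PD fluid libraries. In Mr1-/- PBS replicates 1 and 2 it was 4.34 and 6.11. The camera adjusted p was 0.0030 for heat shock, 0.0040 for oxidative stress, 0.013 for hypoxia, 0.61 for MHC class I and 0.011 for interferon genes, and with an estimated correlation the adjusted p was 0.56, 0.49, 0.42, 0.79 and 0.69. With an adipocyte score as a covariate, a test added after the data were seen, camera called the interferon list higher (adjusted p = 8.8e-11).

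In Mr1-/- mice the immediate early genes Atf3 and Fosb were 1.59 (SE 0.41) and 1.81 (SE 0.49) higher with PD fluid, and the chemokines Ccl2 and Ccl7 2.27 (SE 0.57) and 1.91 (SE 0.53), all without passing. The 19 immediate early genes had a median of 0.31 there and -0.27 in Mr1+/+, with camera adjusted p = 2.4e-07 and 0.49 (adjusted p = 0.19 and 0.78 with an estimated correlation).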
